A study of Saccharomyces cerevisiae with 76 samples.

How the data were processed

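Chromatin endogenous cleavage with sequencing (ChEC-seq) was used to map where proteins sit on the budding yeast genome. A protein is fused to micrococcal nuclease (MNase), calcium is added to permeabilised cells, and the ends of the released DNA fragments mark the places where the fused protein was close to DNA. The tagged proteins were Med8 and Med17, subunits of the head module of the Mediator coactivator complex, and Taf1, a subunit of the general transcription factor TFIID. Free MNase with a nuclear localisation signal, expressed from the MED8 promoter on a plasmid, served as the control for accessible DNA.

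The unit of the deposited files was other than counts or coverage: the authors deposited aligned fragments as BED intervals, with 1 fragment per line, chromosome, start and end. Per the submitters' processing notes the reads were aligned with Novoalign 2.08.03 to the sacCer3 genome. Repeated intervals were present in the deposited files and every copy was counted. No scaling or filtering by the authors was recorded in the files. Gene coordinates came from a RefSeq table of the same assembly, and the strand of each gene was read from its systematic name. No genome sequence was used here, so the lists chosen in advance of genes with a Gcn4 motif or a TATA box were not run.

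Both ends of each fragment were counted on the nuclear chromosomes, leaving out the ribosomal DNA repeats (positions 450000 to 490000 of chromosome XII). This left a span of 12031367 bp. For each of 5984 genes, ends were counted in an upstream window 500 to 150 bp before the start codon, in a core promoter window from 150 bp to the start codon, and in the gene body. Counts were scaled to counts per 1000000 nuclear ends (CPM). A pseudocount of 5 CPM was added before log2 ratios were taken, and a gene entered a comparison if its window had a mean of at least 5 CPM over the libraries compared. Genes whose body held under 10% of the library's median density in any library of a comparison were left out as deleted or unmappable.

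There was 1 library per condition and time, so there were no replicates, no p-values and no paired analysis. Each comparison set 2 time courses side by side at matched times after calcium (30 s, 1 min, 5 min, 10 min and 20 min). The reported value is the mean log2 ratio over those 5 times, and the SD is the spread over times, which is not a replicate error. A gene was called higher or lower when the mean was at least 1 in size and the ratio had the same sign at all 5 times. The size rule was also applied to the 3 pairs of untreated Med8 courses of different strain and date, which shows how many genes pass without any treatment. Shares of ends in single libraries have 95% Wilson intervals, which cover counting error only, since fragments without molecular identifiers are not independent molecules.

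A Mediator-bound gene had an upstream window with a mean log2 ratio to free MNase of at least 1 in both the Med8 and the Med17 course in rich medium. A Taf1-bound gene had a core promoter window with a mean log2 ratio of at least 1 over free MNase on the average of both Taf1 courses. Gene lists were fixed before the data were examined, together with the comparisons, the size rule and most of the alternatives listed further on: Gcn4 amino acid biosynthesis (49 genes), ribosomal protein (137), ribosome biogenesis (37), glycolysis and fermentation (16), heat shock and general stress (29), galactose (6), meiosis and sporulation (15), histone (9), phosphate (12), sulfur (10) and nitrogen catabolite (15). Each list's median log2 ratio was ranked as a percentile among 10000 random lists of the same size matched on mean signal. A list of 21 iron uptake genes was added after the results were seen and is used in the closing part only.

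The rule for named genes, also fixed beforehand, took the 10 genes with the highest and the 10 with the lowest mean log2 ratio among those that passed the size rule and had a standard name, plus a fixed panel (ARG1, ARG3, ARG4, HIS4, HIS5, ILV2, ASN1, LYS20, SNZ1, TRP3, RPL3, PMA1, TDH3, PGK1, CDC19, ADH1, ACT1, HSP12, HSP104, GAL1 and SPO13). The panel held 2 further genes that are not reported here. A gene whose window overlapped one already taken was named with it. Members of the fixed lists outside the rule that are given as examples were chosen after their values were seen.

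The calling step was tested on simulated window counts with known changes. With counts modelled on the comparison of sulfometuron methyl with no drug, 3 of 68 genes with a true log2 change of 1 in size were called, 54 of 66 at 1.5, 54 of 66 at 2 and 0 of 5549 unchanged genes. With counts modelled on the Med14 depletion courses the numbers were 0 of 68, 55 of 66, 62 of 66 and 0 of 5737. For the upstream windows of Med8 over free MNase in YPD they were 25 of 68, 57 of 66, 59 of 66 and 7 of 4669. That run used the size rule, and the rule for Mediator-bound genes in both courses was not simulated. In every run both courses were drawn from the same control values, with counting error and the set changes only. Differences between cultures and dates were left out, so the few calls among unchanged genes are no estimate of false calls between real courses.

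The alternatives tried were scaling each library to its median gene-body density, a pseudocount of 1, no filter on low values, other windows (600 to 100 bp upstream, and 200 bp upstream to 50 bp into the gene), fragments of at most 120 bp, each distinct fragment counted once, only genes whose upstream window overlaps no other reading frame, early times, late times, each time left out in turn, the average of the untreated Med8 courses as the control, and a stricter size of 2 for bound windows. A pooled rule for deleted genes, average profiles over named genes only and a correction for background cutting were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.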

Results

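ChEC-seq libraries were made from budding yeast carrying an MNase fusion to Med8 or Med17, which belong to the head of the Mediator coactivator, or to Taf1, which belongs to TFIID, or expressing free nuclear MNase. The 76 libraries formed 13 time courses after calcium addition, with samples at 0 s, 30 s, 1 min, 5 min, 10 min and 20 min. Both courses of the kin28as strain lacked the 0 s sample. Courses in rich medium (YPD) covered Med8, Med17 and free MNase. The remaining courses were grown in synthetic glucose complete medium without isoleucine and valine (GC) and followed Med8 with or without 0.5 µg/mL sulfometuron methyl (SM), Med17 in a med15 deletion with or without SM, Med8 in the kin28as strain with or without 6 µM NA-PP1, Med8 in a Taf1-FRB strain with or without 1 µg/mL rapamycin, and Taf1 in a Med14-FRB strain with or without rapamycin. There was 1 library per condition and time, and hence no replicates. Nuclear ends outside the ribosomal DNA ranged from 50336 in the 0 s free MNase library to 17130638 in the 5 min library of kin28as with NA-PP1. The free MNase libraries at 30 s and 1 min held 85620 and 76638 such ends, against 977072 or more in every library of a fusion protein.

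The deleted and tagged genes gave a check of the labels. The body of MED15, which encodes the Mediator tail subunit deleted in these strains, had a mean density of 0.10 and 0.09 times the library's mid-level gene in the med15 deletion courses without and with SM, and 0.72 or more elsewhere. The auxotrophy genes LYS2 and MET17 were at or below 0.05 in all 9 courses labelled BY4705, the strain of the Mediator and free MNase courses outside the FRB strains, and between 0.66 and 1.18 in the FRB courses. The MED8 coding region stood at 5.38 to 18.4 in the 7 courses of tagged Med8, and MED17 stood at 2.86 in the Med17 course in YPD. In the Med17 courses of the med15 deletion it stood at 1.37 and 1.19, against 0.53 to 1.17 in courses without tagged Med17, so this check did not show the tag there. FPR1, which encodes the rapamycin-binding protein that anchor-away strains lack, stood at 0.27 and 0.20 in the Taf1 courses and 0.58 in the rapamycin course of the Taf1-FRB strain, but at 1.96 in its untreated course. Before calcium it was at 0.12 and 0.31 in these 2 Taf1-FRB courses, and at 20 min at 1.25 and 1.95. LEU2 and HIS3 stood at or below 0.02 in the med15 deletion and kin28as courses. In the other courses their means were 0.38 or more, but LEU2 was at 0.11 or below at 20 min in free MNase, in Med8 and Med17 in YPD and in both wild type Med8 courses in GC, and HIS3 was at 0.06 to 0.15 at 20 min in Med17 YPD, Med8 YPD and Med8 GC.

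The first question was where Mediator sits upstream of genes. In YPD, 1032 of 4863 measured genes had an upstream window cut more than by free MNase in both the Med8 and the Med17 course, in 852 merged regions. The highest Med8 ratios were at TDH3 (log2 6.18 ± 1.89, SD over times; chromosome VII, 883961 to 884310), ENO1 (5.69) and PGK1 (5.37), which encode glycolytic enzymes, at ADH1 (5.19), the main alcohol dehydrogenase of fermentation, at HXT2 (5.23), a glucose transporter, at BMH1 (5.80), a 14-3-3 protein, at ZEO1 (5.80) and HOR7 (5.54), and at MGA1 (5.73) and TPS2 (5.19), the latter an enzyme of trehalose synthesis. Med17 gave 6.07 at TDH3, 6.05 at MGA1, 6.01 at TPS2, 6.00 at BMH1 and 5.96 at ENO1.

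Glycolysis and fermentation genes were the list most strongly marked by Med8, with 15 of 15 measured members higher than free MNase and a list median of 4.50 ± 0.97, at percentile 100 of matched random lists. In the heat shock and general stress list 19 of 25 rose and 1 fell (2.93), in the histone list 4 of 4 rose (2.54), in the phosphate list 7 of 10 (2.06) and in the sulfur list 7 of 10 (1.44). The Gcn4 amino acid biosynthesis list had 25 higher and 7 lower of 46 (1.18) and the ribosomal protein list 49 higher of 92 (1.10). The ribosome biogenesis list had 1 higher and 14 lower of 31 (-0.94), the galactose list 1 higher and 3 lower of 6 (-1.16), the meiosis and sporulation list 3 lower of 13 (-0.73) and the nitrogen catabolite list 4 higher and 5 lower of 14 (0.03). With gene-body scaling these 4 lists had 6 higher and 1 lower (-0.06), 1 higher and 0 lower (-0.16), 2 higher and 1 lower (0.14) and 7 higher and 1 lower (1.06). DED1 (-4.18) and MRM1 (-4.12) were the lowest, and both lie beside HIS3, the marker of the free MNase plasmid. Scaling to gene bodies moved the median of all genes from -0.23 to 0.80 for Med8 and from -0.35 to 0.83 for Med17 and raised the number of bound genes to 2121, while a size of 2 left 508. The early free MNase libraries were shallow, so the ratios at single genes carry a large counting error.

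Signals of Med8 and Med17 lay close together. Counted for each alone, 1145 genes were bound by Med8 and 1084 by Med17, and 1032 by both. Across 4863 genes the log2 ratios over free MNase had a Pearson r of 0.985 and a Spearman rho of 0.986, and without free MNase the signals had 0.984 and 0.985. Med8 and free MNase had an r of 0.121. Genes are not independent replicates, and simulated courses without binding that shared the free MNase libraries also gave an r of 0.977, but with a covariance of 0.0647 against 2.25 in the data. Between the Med17 and Med8 courses in YPD 36 genes were higher and 12 lower with Med17. PRO3, which lies beside MED17, was highest (2.75), followed by MRK1 (2.66), a glycogen synthase kinase homologue, HXT6 (2.32), a glucose transporter whose sequence is nearly shared with HXT7, PGM2 (2.21), a phosphoglucomutase, and SUC2 (1.74), invertase. AIM4 (-1.74) and MED8 (-1.31) share the tagged locus and were lowest, and the chaperone genes SSA2 (-1.10) and SSE1 (-1.01) were lower too. Heat shock and general stress was the list with the most such genes, 5 higher and 1 lower of 29, and no other list had any. Gene-body scaling gave 55 higher and 5 lower and moved the median of all genes from -0.09 to 0.06.

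Cut positions relative to the start codon were compared between Mediator and TFIID. In the average over all genes, cutting by Med8 and Med17 in YPD was highest 350 bp upstream of the start codon, at 2.55 and 2.58 times the genome mean. Cutting by Taf1 was highest 100 bp upstream (2.40), free MNase 110 bp upstream (2.30) and Med8 in GC medium 170 bp upstream (2.81). These positions changed with time. At 30 s and 1 min Med8 in GC was highest 100 bp upstream, close to Taf1 (100 and 90 bp) and to free MNase (110 bp at both), and at 20 min 350 bp upstream. In YPD Med8 and Med17 were highest 230 bp upstream at 30 s and 90 bp inside the genes at 1 min. Taken as a ratio to free MNase, Taf1 was highest 40 bp upstream. Taf1 marked 536 core promoters, in 519 regions, of 4858 measured, led among named genes by CIT2 (2.18), a citrate synthase, GLC7 (2.09), a protein phosphatase, UBI4 (2.07), polyubiquitin, and CUR1 (2.04). Of the 1030 Mediator-bound and 535 Taf1-bound genes measured in both sets, 266 were shared. The Mediator set came from YPD, and the Taf1 set from the Med14-FRB strain in GC with and without rapamycin. Medium, strain and date thus differ between the sets, and between Taf1 and the free MNase courses in YPD. Taken as a ratio to free MNase, the Med8 and Med17 maxima lay at 320 bp inside the genes, while over named genes only, which leaves out transposon reading frames, they lay 440 bp upstream (position -440), so the position depends on which genes enter the average.

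**Figure D1:**
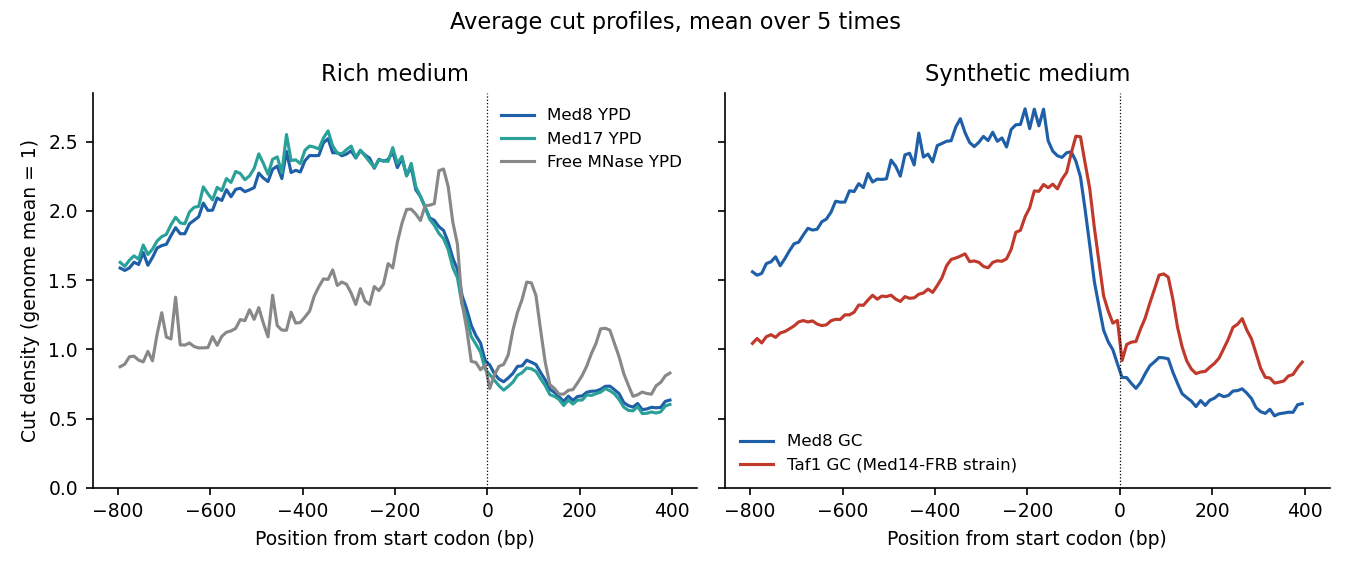
Average density of fragment ends (y, times the genome mean) against the position relative to the start codon (x, bp) over 5252 genes with standard names, mean of the 5 times, 1 line per course. Med8 and Med17 in YPD peak 350 bp upstream (position -350) at 2.52 and 2.58, Med8 in GC at -210 (2.74), and Taf1 and free MNase at -100 (2.54 and 2.30).

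SM inhibits acetolactate synthase, the enzyme encoded by ILV2, and starves cells of isoleucine and valine, which activates the transcription factor Gcn4. The SM courses ask where Mediator goes under that stress. In wild type cells 45 of 5749 upstream windows (41 regions) gained Med8 signal and 11 (9 regions) lost it. In the Gcn4 amino acid biosynthesis list 12 of 47 measured genes rose, none fell and 43 had a positive mean, and the list median was 0.61 ± 0.10 (SD over times), at percentile 100. HIS4, of histidine synthesis, rose by 1.94 ± 0.37 (chromosome III, 68484 to 68833), HOM3, aspartate kinase, by 1.55, ARG4, of arginine synthesis, by 1.39, and ARO4, of aromatic amino acid synthesis, by 1.47. The highest of all was QDR3, a multidrug transporter gene, at 370 CPM with SM against 68.4 CPM without (2.33 ± 0.43).

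The other genes with the highest gains were ARO5 (1.70), ADH5 (1.67), an alcohol dehydrogenase, SDT1 (1.62), a pyrimidine nucleotidase, ORT1 (1.56), the mitochondrial ornithine transporter, TEA1 (1.45), a transcription activator of transposon genes, and the divergent pair SNO1 (1.49) and SNZ1 (1.45) of vitamin B6 synthesis, which share a window. ARG1 (0.79), HIS5 (0.70), ARG3 (0.65), LYS20 (0.66), ASN1 (0.65) and TRP3 (0.44) did not pass, and ILV2 stood at -0.00 (0.17 with gene-body scaling). Signal fell at the iron uptake genes FIT2 (-1.62 ± 0.34), FIT3 (-1.51) and FRE5 (-1.51), at PDR8 (-1.58) with its neighbour BOP2 (-1.56), at CIT2 (-1.20) and at DLD3 (-1.07), the last a D-lactate dehydrogenase of the retrograde response.

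No other list had more than 1 gene that passed. Sulfur had 1 of 10 (median 0.18), and the medians with none were 0.34 for phosphate, with 12 of 12 positive, 0.20 for heat shock and general stress, 0.13 for ribosome biogenesis, 0.05 for nitrogen catabolite and -0.13 for galactose. Ribosomal protein (-0.06), glycolysis and fermentation (-0.01), histone (-0.01) and meiosis and sporulation (-0.05) turned positive with gene-body scaling, at 0.10, 0.16, 0.17 and 0.06. In core promoters 37 genes rose and 13 fell, and 12 of 46 Gcn4 list genes rose (0.56). Gene-body scaling moved the median of all genes from 0.01 to 0.16 and gave 72 higher and 8 lower, and with only genes whose upstream window overlaps no other reading frame 18 rose.

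Med15 is a target of the Gcn4 activation domain in the Mediator tail, and the Med17 courses in the med15 deletion ask how the response depends on it. In the deletion 9 of 5971 upstream windows gained Med17 signal with SM and none lost it. Of the Gcn4 list 6 of 47 rose, 46 had a positive mean and the median was 0.36 ± 0.05, at percentile 100. HIS4 rose by 1.84 ± 0.25, SNZ1 by 1.43 and SNO1 by 1.24, ADH5 by 1.23, ARO1, of aromatic amino acid synthesis, by 1.17, HOM3 by 1.12, ORT1 by 1.06, ARO5 by 1.04 and TMT1, a methyltransferase, by 1.03. No gene of another list passed. The medians were 0.05 for ribosomal protein, 0.04 for ribosome biogenesis, 0.10 for glycolysis and fermentation, 0.11 for heat shock and general stress, 0.10 for phosphate, 0.10 for sulfur, 0.03 for meiosis and sporulation, -0.08 for histone, -0.09 for nitrogen catabolite and -0.01 for galactose (0.06 with gene-body scaling). Core promoters had 3 genes higher, and 2 genes rose among those with an upstream window free of other reading frames.

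The response of the Gcn4 list was larger for Med8 in wild type than for Med17 in the deletion. For the 46 genes measured in both, the medians were 0.61 and 0.33, the median difference at matched times was 0.21 ± 0.10, at percentile 100, and wild type was above in 37 genes. The difference was as large in the phosphate list (0.23 ± 0.10, percentile 99.8, above in 10 of 12) and the nitrogen catabolite list (0.21 ± 0.15, percentile 99.9, above in 11 of 15), so it was not particular to Gcn4 genes. ARO4 had a difference of 0.76 (1.47 against 0.70) and ARG4 of 0.45 (1.39 against 0.93), while HIS4 (1.94 against 1.84) differed by 0.10 and SNZ1 (1.45 against 1.43) by 0.02. No gene of the list passed the size rule on the difference itself. The tagged subunit and the date of the libraries differed along with MED15. The deletion courses also held fewer ends in Mediator-bound windows, 8.65% to 16.0% without SM against 21.6% to 26.8% in wild type. More background shrinks log2 ratios, so the smaller response cannot be put down to the loss of MED15.

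**Figure D2:**
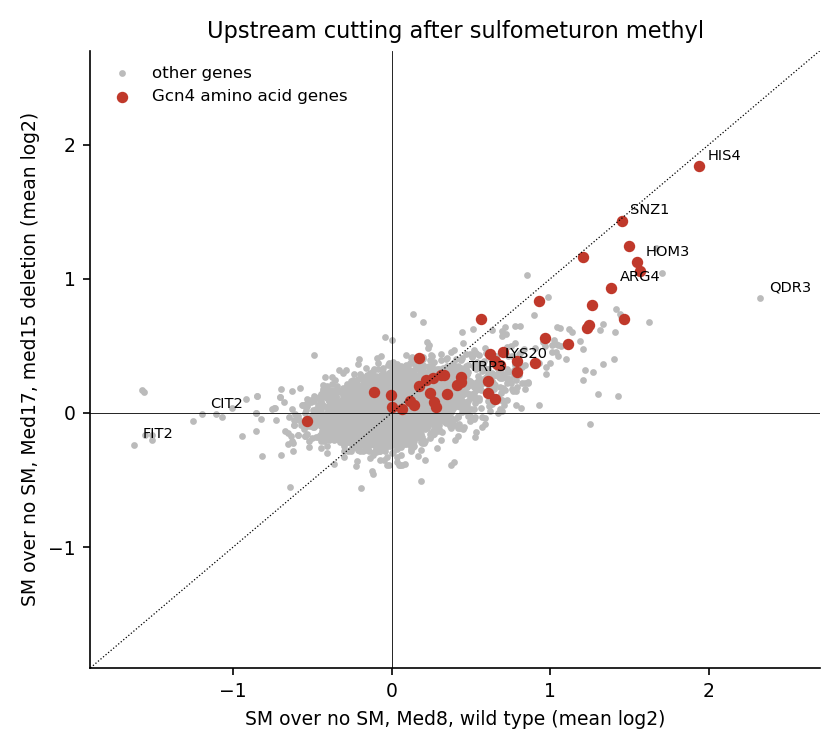
SM response (log2 ratio with SM over without SM, mean of 5 times) for Med8 in wild type (x) and Med17 in the med15 deletion (y). Each point is a gene measured in both, with the Gcn4 list in red and other genes in grey. The Gcn4 list medians are 0.61 and 0.33, 37 of its 46 genes have the larger value in wild type, and HIS4 is at 1.94 and 1.84.

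Without SM, Med17 in the med15 deletion was compared with Med8 in wild type. Scaled to CPM, signal fell at 460 of 5963 upstream windows (371 regions) and rose at 924 (843 regions), with the median of all genes at 0.53. With gene-body scaling that median was -0.47, and 1674 fell and 13 rose. The values that follow are CPM ratios from which that median was not subtracted. Relative to the all-gene median, glycolysis and fermentation stood at -2.48 (-2.63 with gene-body scaling), heat shock and general stress at -1.896 (-2.05), histone at -1.87 (-2.02) and the Gcn4 list at -1.23 (-1.31). The genes of glycolysis and fermentation lost signal throughout, with 15 of 16 lower and a list median of -1.95 ± 0.30, such as TDH3 (-2.46), PGK1 (-2.45), CDC19 (-2.08), pyruvate kinase, and ADH1 (-2.31). In the heat shock and general stress list 20 of 29 fell and 1 rose (median -1.37), with HSP104, a disaggregase, at -1.99, and in the histone list 8 of 9 fell and 1 rose (-1.34). The Gcn4 list had 10 lower and 2 higher of 47 (-0.70), among the lower HIS4 (-1.65), ILV2 (-1.64) and ARG3 (-1.43).

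The largest losses were at MGA1 (-3.71 ± 0.30; chromosome VII, 987549 to 987898), HXT2 (-3.15), the transcription factor genes VHR1 (-3.06), TYE7 (-3.00), an activator of glycolytic genes, and HAP4 (-2.72), of respiration, FMP48 (-2.94), RTS3 (-2.72), and the iron genes FRE5 (-3.00), FIT3 (-2.82), FIT2 (-2.76) and ENB1 (-2.91), a siderophore transporter. The highest were TAH1 (3.02), PWP2 (2.47), VAC17 (2.18) with CHA1 (2.12), a catabolic serine and threonine deaminase, FUN30 (2.07) and DAN1 (1.98), a cell wall mannoprotein. Ribosome biogenesis had 12 higher of 37 (0.81, but -0.07 with gene-body scaling), meiosis and sporulation 6 higher (0.75, but -0.11), nitrogen catabolite 6 higher and 1 lower (0.92, but -0.10), ribosomal protein 2 higher and 4 lower (0.23, but -0.88) and galactose 3 higher of 6 (1.01, but 0.11 with 0 higher and 1 lower). Phosphate had 1 lower (-0.29) and sulfur 1 lower (-0.51), but 10 lower (-1.39) and 8 lower (-1.63) with gene-body scaling. Subunit and date differed too, and the Med17 over Med8 comparison in YPD, with 36 and 12 genes, is the background for the subunit. Gene-body density relative to the genome was 0.57 to 0.82 in the deletion and 0.45 to 0.56 in wild type. Dilution by background cutting was not corrected for here, so it cannot be told apart from a loss at strongly bound genes.

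Kin28 is the kinase of TFIIH that phosphorylates RNA polymerase II, and the kin28as form is inhibited by the ATP analogue NA-PP1. These courses ask where Mediator stays when polymerase cannot leave the promoter. With NA-PP1 Med8 signal rose at 438 of 5284 upstream windows (364 regions) and fell at 60 (55 regions), with the median of all genes at 0.21. The courses with and without NA-PP1 differed in library date. The highest were TPH3 (2.82), BMH2 (2.82 ± 0.65), a 14-3-3 protein, RSB1 (2.80), a sphingoid base transporter, BDH2 (2.77), FLR1 (2.60 ± 1.09), a multidrug transporter, TOH1 (2.57), AIM26 (2.53), ATG40 (2.44), an autophagy receptor, VMR1 (2.25) and TIP41 (2.21). The lowest were CTR2 (-2.27), a vacuolar copper transporter, FZF1 (-2.22), an activator of sulfite efflux, TRX1 (-1.95), thioredoxin, MUD1 (-1.89), SEN15 (-1.75), BIO5 (-1.64) and SUL1 (-1.54), a sulfate permease.

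Genes for ribosomal proteins lost signal as a list, with 29 of 137 lower, 0 higher and a median of -0.64 ± 0.18 at percentile 0, such as RPL39 (-1.70) with RPS22A (-1.69), which share a window, RPL21B (-1.53) and RPS8B (-1.53). Reads of ribosomal protein paralogs are hard to tell apart. Heat shock and general stress had 4 of 29 higher (0.48), the Gcn4 list 2 of 47 higher (0.12), ribosome biogenesis 1 of 27 higher (0.12) and sulfur 1 of 10 lower (-0.35). No gene passed in glycolysis and fermentation (-0.33), histone (0.07) or phosphate (0.06), nor in galactose (-0.09), meiosis and sporulation (-0.07) or nitrogen catabolite (-0.09), of which the last 3 turned to 0.21, 0.12 and 0.15 with gene-body scaling. Of the Mediator-bound genes 111 rose and 19 fell of 1032 (median 0.19), and of the Taf1-bound genes 71 rose and 3 fell (0.37). In core promoters 273 of 3743 rose and 35 fell, and 28 of 127 ribosomal protein genes fell (-0.69). In the untreated kin28as course all 16 glycolysis genes were already lower than wild type in core promoters (-2.04).

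The ribosomal protein genes were higher in the untreated kin28as course than in untreated wild type, by a median of 1.14 ± 0.38 with 74 higher and 3 lower, and with NA-PP1 they stood 0.52 above wild type. Fragments were shorter in both kin28as courses, with medians of 69 to 108 bp. Gene-body scaling moved the median of all genes to 0.48 and gave 1233 higher and 23 lower, with 6 ribosomal protein genes lower and 4 higher (-0.34). It gave 246 higher and 4 lower Mediator-bound genes and 169 higher and 0 lower Taf1-bound genes. Relative to the all-gene median the ribosomal protein list stood at -0.85 with CPM and -0.82 with gene-body scaling. Leaving out the 20 min libraries gave 700 higher and 114 lower, and against the average of the untreated Med8 courses 218 rose, 149 fell and the ribosomal protein median was -0.05.

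Rapamycin moves FRB-tagged Taf1 out of the nucleus, so the Taf1-FRB courses ask how Mediator depends on TFIID. With rapamycin Med8 signal fell at 712 of 5964 upstream windows (559 regions) and rose at 146 (145 regions). Of the Mediator-bound genes 408 of 1032 fell and none rose, with a median of -0.96 ± 0.52. That median was -1.39 at 30 s, -1.56 at 1 min, -0.60 at 10 min and -0.33 at 20 min. The lowest were genes of iron transport, SMF3 (-3.08 ± 0.42; chromosome XII, 212084 to 212433), a vacuolar metal transporter, FRE5 (-2.86) with FIT3 (-2.80), ARN2 (-2.76), FIT2 (-2.68) and ENB1 (-2.51), together with FHN1 (-2.64), BOP2 (-2.63), PAL2 (-2.56), BNA1 (-2.46), of nicotinate synthesis, and PUN1 (-2.37).

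Of the panel, PMA1, the plasma membrane proton pump, fell by 1.71, SNZ1 fell by 1.71, ADH1 fell by 1.63, RPL3 fell by 1.23 and ACT1, actin, fell by 1.07. Heat shock and general stress had 8 of 29 lower (median -0.94), sulfur 3 of 10 (-0.85), glycolysis and fermentation 2 of 16 (-0.82, but -0.45 without the 30 s libraries), ribosomal protein 34 of 137 (-0.73), phosphate 1 of 12 (-0.65), histone 2 of 9 (-0.63), nitrogen catabolite 1 of 15 (-0.29) and the Gcn4 list 4 lower and 1 higher of 49 (-0.15). Ribosome biogenesis had 1 higher of 37 (0.58, but -0.27 with gene-body scaling), meiosis and sporulation 1 higher of 15 (0.44, but -0.44) and galactose none (0.14, but -0.74). The highest genes were ADH4 (3.07 ± 1.39) and MNT2 (2.09), neighbours on chromosome VII, ROK1 (1.43), a helicase of ribosome assembly, MSH5 (1.31), TDA8 (1.30), CTF13 (1.30), HIS7 (1.28), VPS30 (1.27), PPM2 (1.25) and PGU1 (1.23).

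In core promoters 413 of 5911 genes fell and 10 rose, with PDR8 (-2.65) and INO1 (-2.48), of inositol synthesis, lowest and ADH4 (2.60) and HIS4 (2.01) highest. Of the Taf1-bound genes 131 of 536 fell upstream and 1 rose (-0.74). Gene-body scaling moved the median of all genes from -0.06 to -1.01 and gave 3003 lower and 1 higher. Of the Mediator-bound genes 985 were then lower and 0 higher (-1.99). Relative to the all-gene median the Mediator-bound genes stood at -0.90 with CPM and -0.98 with gene-body scaling. Leaving out the 5 min or the 20 min libraries gave 62 or 257 higher genes. The count of higher genes also moved with a smaller pseudocount, with short fragments and without overlapping genes, as given further on. The courses differed in library date, and the glycolysis median went from -2.37 at 30 s to 0.46 at 20 min.

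The share of ends in Mediator-bound upstream windows gave the same loss as a single number per library. At 30 s it was 13.2% without and 3.51% with rapamycin, at 1 min 17.3% and 4.54%, at 5 min 24.3% and 12.4%, at 10 min 24.5% and 18.0%, and at 20 min 23.2% and 21.8%. In the med15 deletion without SM the share was between 8.65% and 16.0% at these times, against 21.6% to 26.8% for Med8 in wild type. The 95% Wilson intervals cover counting error only and were narrow at these depths, such as 3.49% to 3.52% for the 30 s rapamycin library.

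**Figure D3:**
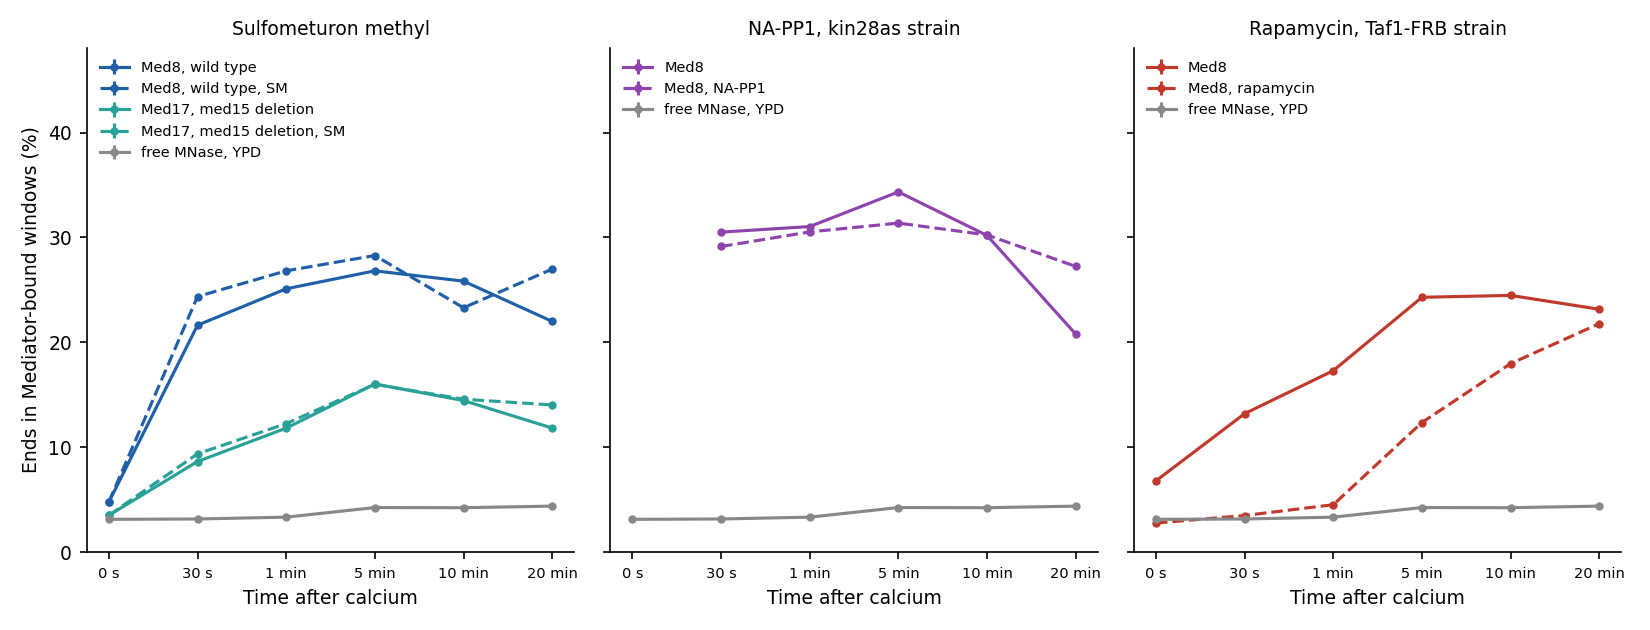
Share of nuclear ends in Mediator-bound upstream windows (y, percent, with 95% Wilson intervals) at each time after calcium (x, categories not to scale), 1 line per course. With rapamycin the Taf1-FRB course climbs from 3.51% at 30 s to 21.8% at 20 min, while its untreated course goes from 13.2% to 23.2%.

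The converse courses ask how TFIID depends on Mediator, with Taf1 followed after Med14, the scaffold subunit of Mediator, was moved out by rapamycin. In core promoters 6 of 5937 genes fell (4 regions) and none rose. The named ones were ITR1, a myo-inositol transporter (-1.17 ± 0.25; chromosome IV, 1445468 to 1445617), the metallothionein pair CUP1-1 and CUP1-2 (-1.02 each), which have the same sequence, and DAL2, allantoicase (-1.01). Upstream 3 of 5964 fell, PUF6 (-1.24), URA8 (-1.11), a CTP synthase, and SGE1 (-1.07), a drug transporter, and none rose. The Taf1-bound genes had a median of -0.24 ± 0.32 with 1 of 536 lower, close to the -0.23 of all genes, and went from 0.24 at 30 s to -0.48 at 20 min. This set was chosen on the average of both Taf1 courses, so genes that lost Taf1 signal with rapamycin were less likely to enter it. Its count and median thus cannot show how often Taf1 was lost. Without rapamycin, core promoter cutting by Taf1 had a median log2 of only 0.40 over free MNase in YPD. At the Taf1-bound genes it was 1.33. Over free MNase, 653 of 4865 measured core promoters passed the size rule as higher and 47 as lower. A fall to the free MNase level could have passed at these 653, and 6 genes passed in all. At the other measured windows such a fall was too small to pass, and a partial loss could be missed at any window. The low count therefore does not show that TFIID is independent of Mediator.

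Among the lists only nitrogen catabolite held a gene that passed, DAL2 (1 of 15, median -0.34). The other core promoter medians were -0.26 for the Gcn4 list, -0.33 for ribosomal protein, -0.04 for ribosome biogenesis, -0.26 for glycolysis and fermentation, -0.36 for heat shock and general stress, -0.05 for galactose, -0.21 for meiosis and sporulation, -0.38 for histone, -0.17 for phosphate and 0.02 for sulfur (-0.07 with gene-body scaling). The mean density of core promoters relative to the genome was 1.36 without and 1.53 with rapamycin at 30 s, 2.33 and 1.68 at 5 min, and 1.95 and 1.37 at 20 min. With the 30 s and 1 min libraries alone 8 genes rose, 1 fell and the Taf1-bound median was 0.014, and leaving out the 5 min libraries left 2 lower genes. With fragments of at most 120 bp 7 rose and 71 fell, a pseudocount of 1 gave 4 higher and 16 lower, with the 3 later times 14 fell, and with distinct fragments or other windows 1 fell. Simulated genes with a true log2 change of 1 were not called (0 of 68), with median estimates of 0.86 and -0.77 against the size rule of 1, while 55 of 66 at a larger change of 1.5 were called. The simulated changes applied to whole window counts, not to the part above free MNase.

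**Figure D4:**
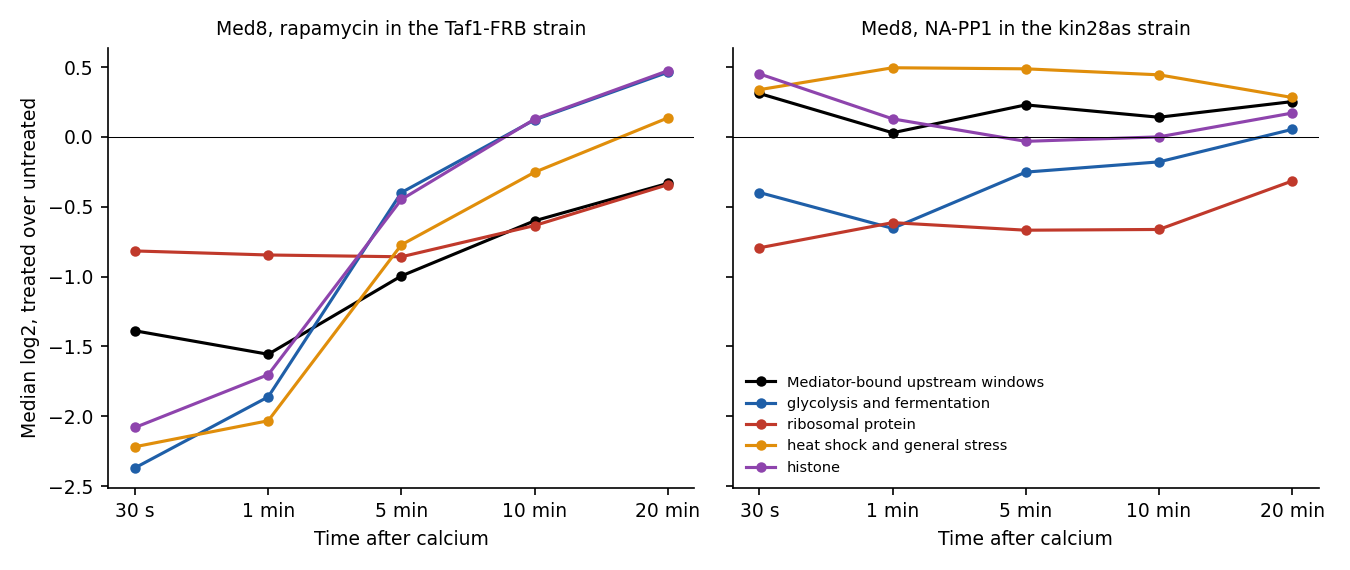
Median log2 ratio of chosen gene sets in upstream windows (y) at each time after calcium (x, categories not to scale), 1 line per set. The panels show Med8 with rapamycin in the Taf1-FRB strain and with NA-PP1 in the kin28as strain. In the Taf1 depletion panel the glycolysis median runs from -2.37 at 30 s to 0.46 at 20 min and the ribosomal protein median from -0.82 to -0.34.

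The Med8 courses in GC and YPD ask how Mediator differs between media, with 1 course in each. In GC medium 87 of 5814 upstream windows rose (76 regions) and 26 fell (23 regions). The highest were genes of iron uptake, FRE5 (4.34 ± 0.29; chromosome XV, 1061064 to 1061413) with FIT3 (4.30), FIT2 (3.99), ARN2 (3.66), FRE3 (2.91), FRE2 (2.46), AAC1 (2.43) with FET3 (2.35), FRE4 (2.24), SIT1 and SMF3 (1.99), and LEU1 (2.29), of leucine synthesis. The lowest were PTR2 (-2.29), a peptide transporter, CTR1 (-1.85), a copper transporter, GTT2 (-1.76), SRP40 (-1.74), HPT1 (-1.59), of purine salvage, KTR2 (-1.30) and TMA19 (-1.21).

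Of the Gcn4 list 6 of 47 rose and none fell (median 0.23), among them SNZ1 (1.65). Heat shock and general stress had 2 higher (0.22), sulfur 1 higher (-0.12, but 0.03 with gene-body scaling) and ribosomal protein 2 lower of 137 (-0.43). No gene passed in ribosome biogenesis (-0.31), glycolysis and fermentation (-0.18), galactose (0.12), meiosis and sporulation (-0.01, but 0.10), histone (0.39), phosphate (-0.29) or nitrogen catabolite (0.06). Gene-body scaling moved the median of all genes from -0.04 to 0.08 and gave 121 higher and 19 lower. Fragments of at most 120 bp gave 131 higher and 80 lower, the 30 s and 1 min libraries alone 97 and 138, a pseudocount of 1 gave 110 and 42, and genes whose upstream window overlaps no other reading frame 50 and 18. The courses differed in date.

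Untreated Med8 courses in GC medium differed from each other by many genes. With CPM each pair with kin28as differed by more genes than passed with SM in wild type (45 higher, 11 lower), NA-PP1 (438, 60) or rapamycin in Taf1-FRB (712, 146). The remaining pair exceeded SM only. With gene-body scaling NA-PP1 (1233 higher, 23 lower) and rapamycin (1, 3003) changed more genes than any pair. Between kin28as and wild type 295 genes were higher and 651 lower, between Taf1-FRB and wild type 206 and 157, and between Taf1-FRB and kin28as 824 and 390. With gene-body scaling these were 356 and 448, 152 and 256, and 306 and 195, and the all-gene medians went from -0.34 to -0.14, from 0.06 to -0.13 and from 0.45 to 0.07, so the direction of the second pair turned. With distinct fragments 454, 295 and 583 genes differed in all. Taf1-FRB over wild type was highest at GIT1 (3.83), a glycerophosphoinositol transporter, DAL80 (3.24), a repressor of nitrogen catabolite genes, with SPO14 (3.28), VBA1 (3.06), DUR12 (3.04), of urea breakdown, and DAL5 (3.03), an allantoate permease, and 10 of 15 nitrogen catabolite genes rose (median 1.18 ± 0.32). HXT7 was lowest (-7.34), at 0.118 against 830 CPM, and its sequence is nearly shared with HXT6. Kin28as over wild type was highest at VAC17 (2.98) with CHA1 (2.73) and at RPL2B (2.72), and lowest at KEI1 (-2.80) and PFK1 (-2.30). At the Mediator-bound windows the medians of these pairs were -0.10, -0.26 and -0.15, smaller in size than the -0.96 of the Taf1 depletion. With gene-body scaling they were 0.22, -0.47 and -0.67, against -1.99, and at 30 s with CPM 0.05, -0.53 and -0.48, against -1.39.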

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

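Among the tests weighed here, only the one on background cutting in the Taf1 depletion was chosen before its result was seen. The tests on library dates, on the untreated kin28as course, on fragment length and on iron uptake genes were chosen only after the result was seen.

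Med8 signal at Mediator-bound windows was lower in the rapamycin course of the Taf1-FRB strain, mostly at early times. Uniform dilution by background cutting would leave few of the 408 lower bound genes lower once 1 background share per library was removed. After that correction 103 of 408 (25.3%) were still lower, and 145 bound genes were lower and 63 higher. The background was the 0 s library of the corrected course, with 2.79% of its ends in bound windows. For untreated Taf1-FRB over wild type, that library held 6.81%, against 3.14% for free MNase at 0 s. That pair is therefore not a like control. There the step left 51 of 101 lower and moved the higher genes from 36 to 99. The share is set on the bound windows, so their median after it (-0.10, and 0.01 in the untreated pair) is fixed by the step, which removes any uniform drop, from background or from a loss of Mediator. Dilution therefore stays open. A difference between library dates could add to the loss. Untreated pairs of different dates differed at these windows by at most 0.26 in median size over all times, 0.53 at 30 s and 0.67 with gene-body scaling, against 0.96, 1.39 and 1.99 in the Taf1 depletion. FPR1 stood at 1.96 in the untreated course and 0.58 with rapamycin on average, but at 0.31 and 0.12 before calcium and at 1.95 and 1.25 at 20 min, so these values do not settle whether the strains differed. Dependence of Mediator on TFIID, which the design was built to show, cannot be told apart from date here.

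Genes for ribosomal proteins were lower with NA-PP1 in the kin28as strain than without it. Fragments over 120 bp are argued against as the whole cause, because with fragments of at most 120 bp the list median was still -0.61. Such fragments already made up 69.7% to 81.7% of the untreated and 52.1% to 74.1% of the NA-PP1 libraries. Lengths below 120 bp were not matched, so a difference within that range stays open. The untreated kin28as course stood apart from the other untreated courses, and against those the NA-PP1 course was higher, not lower, with list medians of 0.52 and 0.48. Strain, date and fragment length also differ in those comparisons, so they do not settle whether the decrease rests on that control course. An effect of Kin28 inhibition itself stays open as an untested explanation, since the kin28as strain has only this control, which has another library date.

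Iron uptake genes moved in comparisons that did not set out to vary iron. The added list of 21 genes had a median of 1.89 in GC over YPD, -1.98 in the Taf1 depletion, -1.51 in the med15 deletion without SM, 0.82 with NA-PP1, -0.39 with SM in wild type and -0.03 with SM in the deletion. In GC over YPD, with NA-PP1 and with SM in wild type 20 of the 21 were measured. The list was written after 12 of its genes had been picked out by their values, so its own percentiles decide nothing. The other 9 genes had medians of 0.83 in GC over YPD (8 measured, percentile 100 of random lists matched on signal) and -1.31 in the Taf1 depletion (percentile 0), which argues against a general change of Mediator signal as the whole cause in these 2 comparisons. In the med15 deletion without SM they had a median of -0.55 (percentile 4.23), which left that explanation open there. With SM these genes had medians of -0.14 in wild type (percentile 0.9) and -0.02 in the deletion (percentile 8.82). With NA-PP1 the median was 0.61 (percentile 88.4). Cultures may differ in iron without treatment, since these 9 genes lay below untreated wild type in untreated Taf1-FRB (median -0.56, percentile 0.94), against -1.31 in the Taf1 depletion. The other untreated pairs were less extreme, at -0.13 for kin28as over wild type (percentile 46.3) and -0.42 for Taf1-FRB over kin28as (percentile 6.5). A treatment effect and a culture difference cannot be told apart with 1 culture each. No biological explanation was tested.

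Opposite directions in 2 groups or times drew attention to 7 further list values, and none of these differences was tested. For times, the medians at 30 s and 1 min had to lie beyond 0.1 on one side of 0 and those at 10 and 20 min on the other. This was searched only in upstream windows for the Taf1 depletion and NA-PP1 and in core promoters for the Med14 depletion. Other windows and the untreated pairs were not searched and may hold such lists too. The nitrogen catabolite list differed by 0.21 between the SM response of wild type Med8 and that of Med17 in the med15 deletion. In the Taf1 depletion the median at 20 min minus that at 30 s was 1.30 for the Gcn4 list, 2.83 for glycolysis and fermentation, 2.55 for histone and 1.72 for nitrogen catabolite. In the Med14 depletion it was -1.04 for histone and -0.95 for sulfur. Heat shock and general stress in the Taf1 depletion (-2.22 at 30 s, 0.14 at 20 min) and glycolysis in the Med14 depletion (0.49 and -0.61) changed sign as well but missed this rule at 10 min and 1 min.

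Libraries taken before calcium entered no comparison except as the background of the correction above. They held more ends in Mediator-bound windows in 7 of 10 courses than free MNase at 0 s (3.14%, 95% Wilson interval 2.99 to 3.30). The shares were 14.9% for Med8 and 13.1% for Med17 in YPD, 4.79% for Med8 in GC without SM and 4.79% with SM, 3.53% for Med17 in the med15 deletion without SM and 3.53% with SM, and 6.81% for Med8 in the untreated Taf1-FRB strain. The other 3 lay below it, at 2.79% for Med8 in Taf1-FRB with rapamycin and 2.61% and 2.54% for Taf1 without and with rapamycin. The bound windows were chosen on the later libraries of the YPD courses.

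Regions within 100 bp of tRNA genes, which no comparison uses, held more ends at 20 min than in free MNase (1.46%) in 10 of 12 courses. The shares were 2.22% for Med8 and 2.49% for Med17 in YPD, 2.13% for Med8 in GC and 1.85% with SM, 2.12% for Med17 in the med15 deletion and 2.47% with SM, 3.25% in kin28as and 2.53% with NA-PP1, 2.01% for Med8 in untreated Taf1-FRB and 1.496% for Taf1 in untreated Med14-FRB. The rapamycin courses lay below free MNase, at 1.41% for Med8 in Taf1-FRB and 0.967% for Taf1. Taf1 in untreated Med14-FRB lay below free MNase at each earlier time, such as 1.21% against 1.48% at 5 min.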

How the results depend on the processing

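Tests with named genes only, a pooled rule for deleted genes and a correction for background were chosen after the data were seen, and the others before the data were examined. The free MNase libraries were the shallowest, with 85620 and 76638 ends at 30 s and 1 min. In a simulation chosen after the data were seen, genes raised over them by 1.5 were called in 98 of 100 cases and genes lowered in 76 of 100. With each free MNase library as deep as at 20 min these were 100 and 96, so depth limited the calls of lower genes more than those of higher ones. At log2 1, the size rule itself, 36 and 18 were called, and 4 and 1 with more depth. Of the values that answer a comparison, 344 stayed within 1.5 times the count or 1 SD, 88 moved and 1 reversed, and of the others 187 stayed, 43 moved and 4 reversed. No low filter, the pooled rule and other bound sets moved none of the values listed here. Cut maxima were not run under other scaling, pseudocount, filter or windows, which do not enter them. No paired analysis was possible because there was 1 culture per condition. Unless stated, the cause was not tested.

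With gene-body scaling 2121 genes were bound, SM in wild type raised 72 genes, and the Gcn4 medians were 0.81 in wild type and 0.43 in the deletion, with a difference of 0.31. NA-PP1 raised 1233 and lowered 23 (bound median 0.63), Taf1 depletion 1 and 3003 (bound median -1.69). These bound medians are over the bound genes of that scaling, and over the 1032 of CPM scaling they were 0.52 and -1.99. It also gave 13 higher and 1674 lower in the med15 deletion without SM, with its all-gene median reversed from 0.53 to -0.47, and 501 genes differed between Taf1-FRB and kin28as. This scaling sets gene bodies equal, so it shifts all windows of a library together.

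With a pseudocount of 1, NA-PP1 lowered 96 genes, Taf1 depletion raised 572, Med14 depletion raised 4 and lowered 16, the med15 deletion raised 1709 and GC medium lowered 42. Other windows gave 227 higher in Taf1 depletion and 1 lower in Med14 depletion.

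With short fragments r was 0.981, the Taf1 cut maximum lay at -170, SM raised 17 genes in the deletion, Taf1 depletion raised 310, Med14 depletion raised 7 and lowered 71, GC medium raised 131 and lowered 80, and 555 genes differed between Taf1-FRB and wild type. With distinct fragments the Med8 and Med17 cut maxima lay at -480 and -480, NA-PP1 raised 268 and lowered 36, Med14 depletion lowered 1, the med15 deletion raised 611, and 454 (kin28as over wild type) and 583 (Taf1-FRB over kin28as) genes differed.

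With genes without overlap, which are fewer, r was 0.983, the Med8 GC cut maximum lay at -440, SM raised 18 genes in wild type and 2 in the deletion, NA-PP1 raised 235, Taf1 depletion 35, the med15 deletion 329 and GC medium 50, Med14 depletion lowered 0, and 566, 212 and 686 genes differed between untreated courses.

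With 30 s and 1 min only, r was 0.982, cut maxima lay at -480 for Med8 and Med17 and -90 for Taf1, the SM difference was 0.31, NA-PP1 raised 809 and lowered 132, Taf1 depletion 74 and 1193, Med14 depletion 8 and 1 with its Taf1-bound median reversed to 0.014, GC medium lowered 138, and 2582 genes differed between Taf1-FRB and kin28as. With 5, 10 and 20 min only, the Med17 cut maximum lay at -590, Taf1 depletion raised 296 with its glycolysis median reversed to 0.068, and Med14 depletion lowered 14.

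Against the mean of the untreated controls, SM lowered 126 genes in wild type, NA-PP1 raised 218 and lowered 149 with its all-gene median reversed to -0.10, and Taf1 depletion raised 449. A threshold of 2 left 508 bound genes. Named genes only gave cut maxima at -440 and -440. After the background correction Taf1 depletion lowered 1080 genes, its bound median, fixed by the step, was -0.10 and its glycolysis median reversed to 0.98.

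Leaving out 1 time gave 62 to 257 higher genes in Taf1 depletion, where leaving out 30 s gave 243, 5 min 62 and 20 min 257, and glycolysis medians there from -1.14 to -0.45 (without 30 s). It gave cut maxima from -480 to 320 for Med8 and Med17 (without 5 min and 1 min, -480 and -440), 2 to 8 lower (2 without 5 min, 3 without 1 min) and 0 to 1 higher genes in Med14 depletion, and 370 to 700 higher and 50 to 114 lower genes with NA-PP1, the upper values without 20 min.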

Other observations

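The nitrogen catabolite list, which holds transporters and enzymes for poor nitrogen sources, had 10 of 15 genes higher in untreated Taf1-FRB than in wild type (median 1.18 ± 0.32, SD over times, single genes from -0.29 to 3.24). With rapamycin 6 of 15 were higher than wild type (0.88 ± 0.55, from -0.51 to 3.15), and in untreated kin28as 2 of 15 (0.33 ± 0.08). These comparisons share the wild type course. Against untreated kin28as 9 of 15 were higher in Taf1-FRB (1.26 ± 0.33), and with rapamycin 7 were higher and 1 lower (1.14 ± 0.74). The comparisons of the rapamycin course with wild type and with kin28as were chosen only after the result was seen. Against wild type that course also had 19 of 21 genes of the added iron uptake list lower and 1 higher (-2.46 ± 0.41) and 31 of 137 ribosomal protein genes lower (-0.73 ± 0.39).

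After background correction, which rests on a signal share of 0.0612 at 30 s, the list medians of the Taf1 depletion changed. Glycolysis and fermentation had 8 of 16 higher (median 0.98), histone 6 of 9 higher (1.13) and the Gcn4 list 22 higher and 3 lower of 49 (0.85), while ribosomal protein had 19 lower and 1 higher of 137 (-0.40) and iron uptake 15 lower of 21 (-1.76). Heat shock and general stress went from -0.94 to 0.43, nitrogen catabolite from -0.29 to 0.76, phosphate from -0.65 to 0.03, sulfur from -0.85 to -0.13, ribosome biogenesis from 0.58 to -0.44, meiosis and sporulation from 0.44 to -0.18 and galactose from 0.14 to -0.11. The same correction of untreated Taf1-FRB over wild type raised the higher bound genes from 36 to 99 and gave -0.06 for glycolysis and fermentation, -0.06 for histone, 0.19 for the Gcn4 list, with 5 higher and 2 lower of 48, 0.06 for ribosomal protein and -0.73 for iron uptake, with 8 lower and 1 higher of 21. It also moved ribosome biogenesis from 0.08 to -0.56, meiosis and sporulation from 0.10 to -0.64 and galactose from 0.15 to -0.41, so the same 3 lists turned negative without treatment. Its background was the 0 s library of the untreated Taf1-FRB course, not that of the rapamycin course, so the 2 corrections removed unlike backgrounds. Phosphate stood at -0.48 after the correction of the untreated pair, sulfur at -0.10, heat shock and general stress at 0.02 and nitrogen catabolite at 1.29, with 11 of 15 higher.

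The body of LEU2, a marker gene, stood at 0.87 to 1.28 times the mid-level gene at 0 s in Med8 YPD, Med17 YPD and Med8 GC and at 0.04 to 0.11 at 20 min. HIS3 went from 30.0 to 0.15 in Med8 GC and from 7.19 to 0.11 in Med8 YPD. FPR1 went from 0.31 to 1.95 in the untreated Taf1-FRB course and from 0.12 to 1.25 in its rapamycin course.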
